A study of Mus musculus with 4 samples.

How the data were processed

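RNA-seq was run on flow-sorted 4N retinal cells of postnatal day 2 mice, with 2 GFP-negative libraries labelled wild type and 2 GFP-positive libraries labelled Casz1 cKO. Per the labels' protocols, cells were taken from freshly dissected retinas, held in serum-free medium and sorted into lysis buffer, and a stranded mRNA kit was used. The design text speaks of 2 independent experiments, and how many animals each library holds is not given in the sources used here. Per the submitters' processing notes the tools were FastQC, TopHat, HTSeq and DESeq with the mouse build mm10; versions, settings, the annotation release and whether counting used strand are not given in the sources used here. Without a stated strand setting, reads of a gene and of an overlapping antisense gene cannot be told apart.

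The deposited table holds normalized counts, a signal per gene and library that is each read count divided by 1 size factor per library, per the file headers and the values. All values (100%) came out as whole multiples of the value of 1 read per column within 0.01 reads, so reads were recovered from them. Genes at 0 numbered 6169 and 5793 of 22690 in the wild-type libraries A and B and 9179 and 5992 in the cKO libraries A and B. A normalized count of 8.38 stands for 3 reads in cKO library A, and 1.98 to 2.28 does in the others, and such floors cover counting error only. The column names carry 2 numeric tags, written A and B here. The file heads both cKO columns as replicate 2, so these columns were assigned to their group and not to a numbered sample. The authors' fold column, per the file headers, equals the ratio of the group means in all 16463 rows with a number. The authors' column headed Log2FC holds the log10 of that ratio in all 16463 rows, to 1e-06. The authors' p-value and adjusted p-value columns in the deposited table have values for 17477 genes; of the 5213 without, 5195 have no reads.

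Libraries of one group were compared by a chi-square of their reads across genes, which gave 77.1 per degree of freedom for wild type and 131 for cKO, so in neither pair do the libraries agree within sampling noise. Genes with a mean normalized count of at least 10 were tested (14480) on log2(normalized count + 1) with limma, a moderated two-sided test with a mean-dependent prior, and Benjamini-Hochberg adjustment at 0.05. Fold changes are differences of means on this log2 scale. The added 1 shrinks the ratios of low genes, but a 0 in a single library can also make a fold change large. Lin28b, at 0 in cKO library A, had a log2 fold change of −3.67 with means of 153 in wild type and 72.4 in cKO. A design of 2 libraries per group leaves 2 residual degrees of freedom before moderation. On simulated reads with the spread of all 4 libraries limma recovered 22% of 100 genes changed 2-fold and 82% of 100 changed 4-fold among 14480 genes. With the spread of the libraries other than cKO library A it recovered 90% and 100%. Both simulations had 2 libraries per group, changed only genes with a mean of at least 100 and gave every library the same spread. In the data cKO library A was noisier than the others, so these shares can overstate recovery. There 0 of 12 microglial markers passed over all genes, at a median log2 fold change of −2.72. In the first simulation limma made 12 false calls, edgeR 13 and DESeq2 52.

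Before the data were examined, 33 gene lists were fixed for retinal cell types, other cell types that the gate could hold, position, timing, pathways and complexes. Lists with at least 4 tested members (31) were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. Of these, 8 passed with the preset and 0 with the estimated one. The estimated version tests on the 2 residual degrees of freedom, so it has little power here. Its unadjusted camera p was 0.0374 for the rod list, at an estimated correlation of 0.048. For the other lists that passed with the preset it was 0.159 to 0.284. The rule for named genes, set at the same time, was Casz1, the genes that passed, or failing that the 8 per direction with the smallest p, a mean of at least 50, no overlap between the groups and no predicted or clone name. It also takes, in each list, up to 4 members that passed or else the 2 members with the highest mean. Members are named here for the lists that passed only, and the rod list members that passed over the list alone are named by the same rule in full. The sex-linked genes of the rule are given among the other observations.

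Alternatives were other pseudocounts (0.5 and 5), no filter on low values, a mean of at least 50, a median rescaling of each library, limma without the mean-dependent prior, edgeR and DESeq2 on the recovered reads, a block for the shared numbers and leaving out each library in turn. Coordinates come from GENCODE M21 on GRCm38, where 21798 of the 22690 gene identifiers were found (96.1%). The software was R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.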

Results

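RNA was sequenced from retinal cells of postnatal day 2 mice that had been sorted by flow cytometry for a 4N DNA content, the content of cells that have replicated their genome and not yet divided. The labels give 2 groups of 2 libraries. The GFP-negative cells are labelled wild type and the GFP-positive cells are labelled as carrying a conditional knockout (cKO) of Casz1, a zinc finger transcription factor. The sorted fraction therefore differs between the groups together with the genotype. Each column name carries 1 of 2 tags, called A and B here, each on 1 library of each group, and the libraries are named by these tags. Reads in genes numbered 75832360 in wild-type library A, 83753377 in wild-type library B, 22326119 in cKO library A and 89473701 in cKO library B. Per the series title, the comparison addresses the transcripts of Casz1 conditional mutant progenitors; the cells are named here by their labels.

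The level of Casz1 itself was lower in both GFP-positive libraries than in both GFP-negative ones. Casz1 (ENSMUSG00000028977, a protein-coding gene on chromosome 4, 148804429 to 148954889 of GRCm38, plus strand) had normalized read counts of 13162 and 11995 in the wild-type libraries A and B and of 8687 and 10772 in the cKO libraries A and B. The means were 12579 ± 826 (SD, n = 2) in wild type and 9729 ± 1475 (SD, n = 2) in cKO, which is 77.3% of wild type. The log2 fold change was −0.38 with a standard error of 0.19, and the limma test over all genes gave an adjusted p = 0.771. Within tags the log2 ratio was −0.60 at tag A and −0.16 at tag B. Reads counted over the whole gene can come from exons outside a deleted part, so this level does not measure the deletion.

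Rod and cone photoreceptor genes and microglial genes were lower as groups in GFP-positive cKO cells, and genes of the cell cycle were slightly higher. Each of these list calls was made by camera of limma with a preset correlation and was lost with an estimated one (adjusted p = 0.620 with an estimated correlation). The estimated version tests on 2 residual degrees of freedom, so that loss does not tell correlated members from low power. The rod, S-phase and G2/M calls were each also lost when some single library was left out, as given with each list. Nr2e3, a nuclear receptor of rod photoreceptors, had a mean of 20720 ± 1511 (SD, n = 2) in wild type and 9113 ± 2199 (SD, n = 2) in cKO, a log2 fold change of −1.20 with a standard error of 0.23. Cldn1, a tight junction protein, had 242 ± 13.8 (SD, n = 2) and 711 ± 109 (SD, n = 2), a log2 fold change of 1.54 with a standard error of 0.28. Over single genes, no change passed in limma: 0 of 14480 genes had an adjusted p under 0.05, the lowest adjusted p was 0.771, and 274 genes had an unadjusted p under 0.05. On the recovered reads edgeR called 0 genes, with 208 at an unadjusted p under 0.05, and DESeq2 called 2, Cldn1 higher and Nr2e3 lower, the genes that were named because the count is small. cKO library A stood apart: its Pearson correlation with the other libraries across genes was 0.902 to 0.918, against 0.988 to 0.993 among the other 3. The highest, 0.993, was between cKO library B and wild-type library B, above the 0.990 of the wild-type pair. Without that library limma called 76 genes, 3 higher and 73 lower in cKO, with the lone cKO library assumed to vary like the wild-type pair. Of the lower genes, 72 were also lower in cKO library A than in both wild-type libraries. The same wild-type libraries selected these genes, and the share over all genes was not computed, so this is not an independent check. Without cKO library B limma called 5662 genes, 1846 higher and 3816 lower, under the same assumption.

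The genes with the smallest p in each direction are given as values, since none passed in limma. Among the higher ones, Col11a1, a fibrillar collagen chain, had 1212 ± 126 (SD, n = 2) in wild type and 2845 ± 765 (SD, n = 2) in cKO. Nell2, a secreted neural glycoprotein, had 1361 ± 102 (SD, n = 2) and 3001 ± 806 (SD, n = 2). The log2 fold changes were 1.21 for Col11a1, 1.12 for Nell2, 0.69 for Fam189a2, 0.59 for Itm2a, 0.64 for Igfbpl1, 0.52 for Zfp503 and 0.72 for Gfra2, a receptor of the GDNF family. Among the lower ones, Cngb1, a subunit of the rod cyclic nucleotide-gated channel, had a log2 fold change of −1.25 and Slc1a7, a glutamate transporter of the retina, had −1.01. Pitpnm3, a membrane-associated phosphatidylinositol transfer protein, had −1.62. Sall1, a zinc finger transcription factor also expressed in microglia, had −1.74, Slco2b1, an organic anion transporter, had −1.88, Hmha1 had −2.36 and Otop3 had −0.85. The rule that chose these genes required that the groups not overlap, which held for 5722 of the 14480 genes, 39.5%, where chance gives 33.3%.

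**Figure D1:**
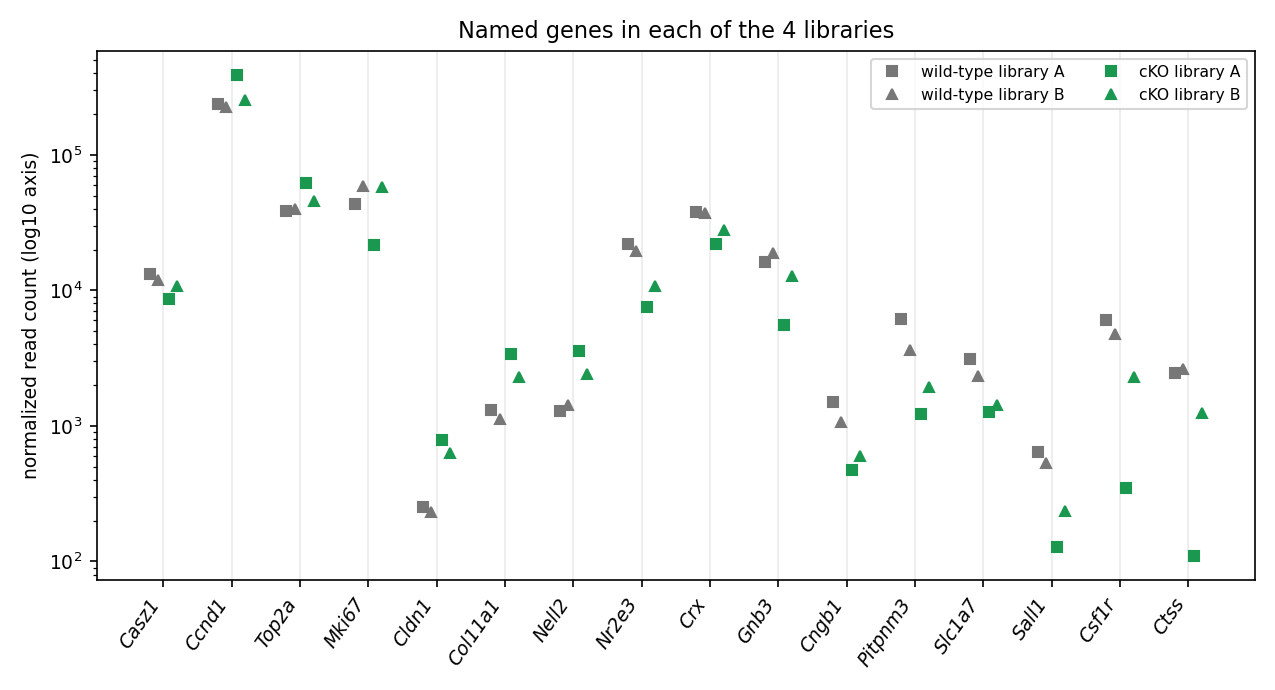
Normalized read counts on a log10 axis for 16 named genes, with 1 point per library, grey for GFP-negative wild type and green for GFP-positive cKO, squares for tag A and triangles for tag B. Csf1r and Ctss lie far lower in cKO library A (346 and 109.0) than in cKO library B (2293 and 1249), and both cKO libraries lie below both wild-type libraries.

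Rod and photoreceptor precursor markers fell as a group. Of 20 tested members, 18 were lower in cKO, with a median log2 fold change of −0.76 (camera of limma, adjusted p = 6.02e-09; adjusted p = 0.620 with an estimated correlation). The median was −0.82 at tag A and −0.61 at tag B, and 18 and 19 of the 20 members were lower there. Without cKO library B the median was −0.63 and the call was lost (camera of limma, adjusted p = 0.0734), and without cKO library A the median was −0.63 and the call was kept (adjusted p = 3.54e-15). With p-values adjusted over the list alone 7 members fell in limma: Nr2e3, Sag, Pde6b, Mpp4, Samd7, Rp1 and Aipl1, against 0 when adjusted over all genes. Crx, the homeodomain factor of photoreceptors, had 37552 ± 792 (SD, n = 2) in wild type and 24933 ± 4262 (SD, n = 2) in cKO, a log2 fold change of −0.60. Sag, rod arrestin, had −0.75, Pde6b, a rod phosphodiesterase subunit, had −1.05 and Samd7 had −1.19. Cone markers fell as a group too: 12 of 12 tested members were lower, with a median of −0.78 (camera of limma, adjusted p = 0.000123; adjusted p = 0.620 with an estimated correlation). Gnb3, a transducin subunit, had −1.05 and Gngt2, another one, had −0.36. No cone marker passed in limma over the list alone. The medians of the cone list were −0.80 at tag A and −0.60 at tag B, and the median was −0.45 without cKO library A. Microglial markers were lower in the same libraries, with a median log2 ratio of −1.21 at tag B.

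Microglial markers showed the lowest median of all tested lists. All 12 were lower in cKO, with a median log2 fold change of −2.72 (camera of limma, adjusted p = 2.43e-06; adjusted p = 0.620 with an estimated correlation). The median was −4.23 at tag A and −1.21 at tag B, and all 12 were lower in both. The list kept its call when either cKO library was left out, with a median of −1.20 without cKO library A and −4.07 without cKO library B. Csf1r, the receptor that microglia need for survival, had 5405 ± 872 (SD, n = 2) in wild type and 1320 ± 1376 (SD, n = 2) in cKO, a log2 fold change of −2.59 with a standard error of 0.84. Ctss, a lysosomal protease of microglia, had 2544 ± 107 (SD, n = 2) and 679 ± 806 (SD, n = 2), a log2 fold change of −2.78. No microglial marker passed in limma over the list alone, although 9 of the 12 had an unadjusted limma p under 0.05 in this comparison. Among the 76 genes called without cKO library A, 10 were members of the microglial list and 6 of the rod list.

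Genes of the cell cycle and of progenitors rose as groups by small amounts, and each list had a larger median at tag A, that of the cKO library that stands apart, than at tag B. S-phase genes had a median log2 fold change of 0.25, with 16 of 18 higher (camera of limma, adjusted p = 0.000434), and G2/M-phase genes had 0.38, with 18 of 20 higher (adjusted p = 0.000493); both had an adjusted p = 0.620 with an estimated correlation. At tag B the medians were 0.12 for S phase and 0.10 for G2/M, against 0.34 and 0.62 at tag A. Rrm1, a ribonucleotide reductase subunit, had a log2 fold change of 0.50, Mcm6, a helicase subunit, had 0.27 and Top2a, a topoisomerase of dividing cells, had 0.45. Mki67, the gene of the Ki-67 proliferation antigen, went the other way with −0.51, from 43005 and 58941 in the wild-type libraries A and B and 21523 and 57702 in the cKO libraries A and B. Without cKO library A the G2/M median was 0.05 and its call was lost (camera of limma, adjusted p = 0.285), and without cKO library B the median was 0.65. The S-phase call was kept without cKO library A, with a median of 0.22 (camera of limma, adjusted p = 0.000193). It was lost without wild-type library A, with a median of 0.13 (camera of limma, adjusted p = 0.116), and without cKO library B, with a median of 0.26 (adjusted p = 0.0767). Core progenitor genes had a median of 0.14 with 13 of 16 higher (camera of limma, adjusted p = 0.0157; adjusted p = 0.620 with an estimated correlation). In that list Ccnd1, a G1 cyclin, had 0.45 and Pax6, an eye field transcription factor, had −0.15. Retinoic acid metabolism genes had a median of 0.42 with 10 of 12 higher (camera of limma, adjusted p = 0.00852; adjusted p = 0.620 with an estimated correlation), with Crabp1, a retinoic acid binding protein, at 0.49 and Rdh10, a retinol dehydrogenase, at 0.38. The retinoic medians were 0.53 at tag A and 0.08 at tag B. Subunits of NuRD, a chromatin remodelling complex, had a median of 0.15 with 12 of 15 higher (camera of limma, adjusted p = 0.0336; adjusted p = 0.620 with an estimated correlation), with Chd4 at 0.06 and Rbbp4 at 0.35. Progenitor, retinoic and NuRD calls were lost without cKO library A, with medians of 0.11, 0.27 and 0.05 (camera of limma, adjusted p = 0.0852, 0.0522 and 0.380). They were also lost without cKO library B, with larger medians of 0.20, 0.51 and 0.26 (camera of limma, adjusted p = 0.0864, 0.159 and 0.0767). Without wild-type library A the calls were lost with medians of 0.12, 0.21 and 0.18 (camera of limma, adjusted p = 0.103, 0.141 and 0.0585). The NuRD call was lost without wild-type library B as well, with a median of 0.22 (camera of limma, adjusted p = 0.129). The microglial median lay at −4.23 at tag A, where these lists had their higher medians.

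Lists of other retinal neurons did not pass with all 4 libraries. Ganglion cell markers had a median log2 fold change of 0.02, with 9 of 16 higher (camera of limma, adjusted p = 0.634), amacrine and horizontal cell markers −0.03 (adjusted p = 0.801) and bipolar markers −0.13 (adjusted p = 0.703). The ganglion median was 0.42 without cKO library A and 0.29 without wild-type library B. These fits set 1 library against 2, so a difference between the tags enters them as a difference between the groups. Within tags the ganglion median was −0.11 at tag A and 0.09 at tag B. With all 4 libraries the ganglion list had adjusted p = 0.958 with an estimated correlation, and the estimate was high, at 0.744. Mueller glia markers had 0.31 (camera of limma, adjusted p = 0.0600) and retinal astrocyte markers −0.35 (adjusted p = 0.0683). The astrocyte median was −0.67 without cKO library A and −0.62 without wild-type library B, and within tags it was −0.35 at both. With all 4 libraries the astrocyte list had adjusted p = 0.620 in camera of limma with an estimated correlation. Endothelial and mural markers had −0.03 (camera of limma, adjusted p = 0.970), pigment epithelium markers 0.02 (adjusted p = 0.970) and 4 crystallin genes did not pass (adjusted p = 0.0767). All 4 tested crystallin genes were at 0 in cKO library A, so the crystallin median is set by the pseudocount there and is not a measured size; at tag B it was −0.28. Genes that mark position across the retina had medians of 0.04 for dorsal (camera of limma, adjusted p = 0.332), 0.21 for ventral (adjusted p = 0.0600), 0.20 for nasal (adjusted p = 0.272), 0.10 for temporal (adjusted p = 0.272) and −0.04 for the ciliary margin (adjusted p = 0.503).

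Genes of developmental timing and of signalling did not pass either. Early-stage temporal genes had a median log2 fold change of −0.13 (camera of limma, adjusted p = 0.531), late-stage temporal genes 0.20 (adjusted p = 0.272) and neurogenic progenitor genes 0.09 (adjusted p = 0.344). Notch pathway genes had 0.18 (camera of limma, adjusted p = 0.177) and Hedgehog pathway genes 0.06 (adjusted p = 0.201). Polycomb subunits had −0.14 with 17 of 24 lower (camera of limma, adjusted p = 0.224) and nuclear lamina genes 0.00 with 7 of 14 higher (adjusted p = 0.531). Immediate-early and heat-shock genes had 0.13 (camera of limma, adjusted p = 0.625), interferon-stimulated genes −0.53 (adjusted p = 0.223) and p53 target genes 0.08 (adjusted p = 0.970). The mean and the median, or the camera direction, differed in sign for the ganglion, ciliary margin, pigment epithelium, immediate-early and p53 lists. Of the Hox list 0 members and of the erythroid list 1 member reached the level filter, so neither was tested.

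**Figure D2:**
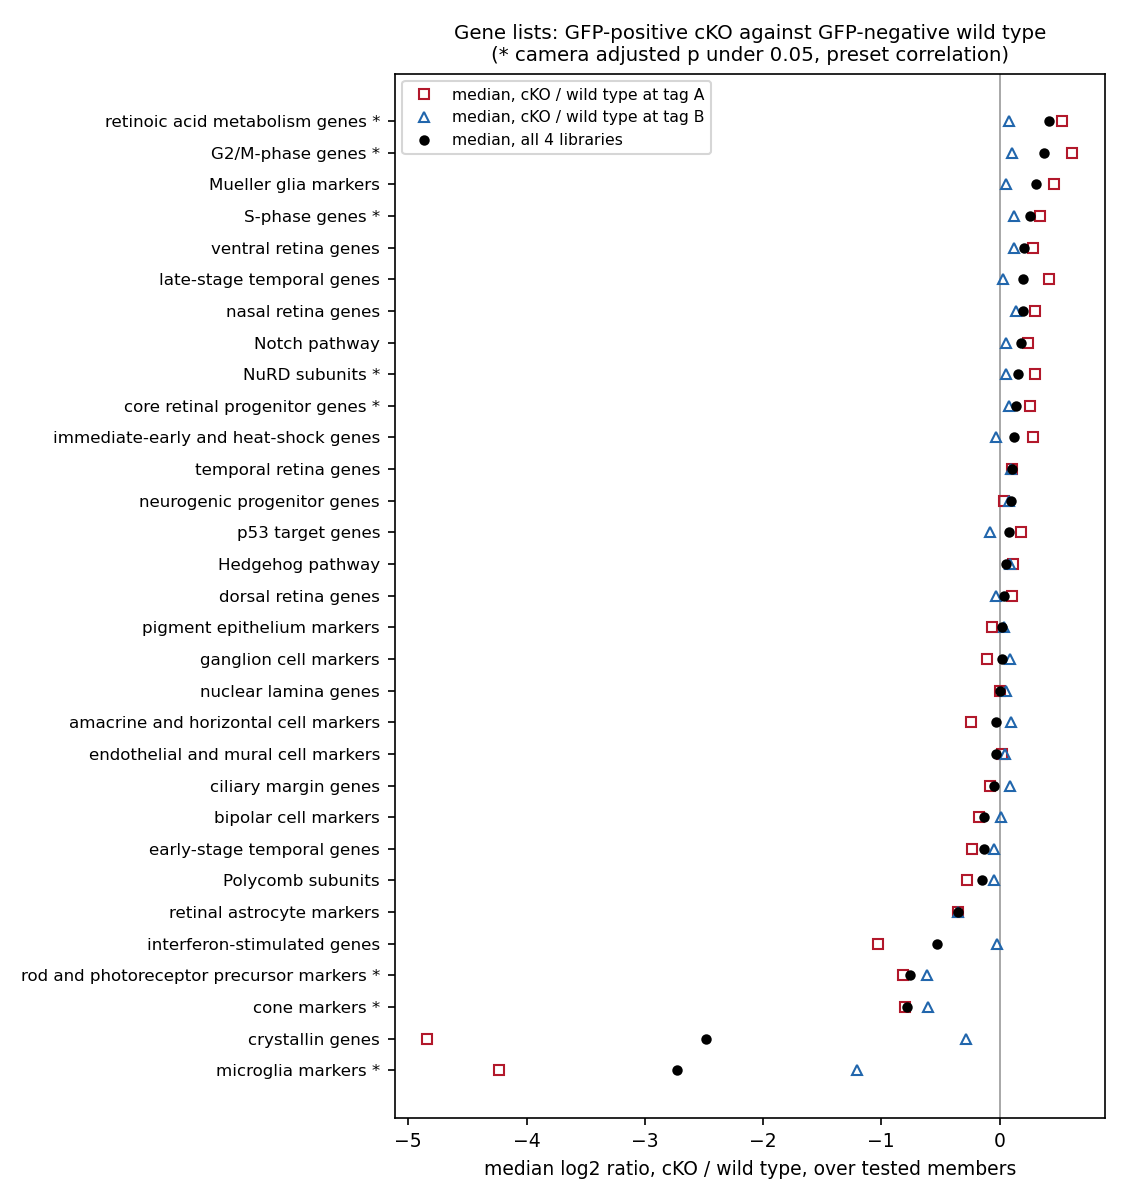
Median log2 ratio of cKO to wild type over the tested members of each of 31 gene lists, with black points for all 4 libraries, red squares for tag A and blue triangles for tag B; a star marks a camera adjusted p under 0.05 with the preset correlation. Microglial markers (−2.72) lie lowest, and rod (−0.76) and cone (−0.78) markers lie below 0 in both tags. The crystallin points for tag A and for all 4 libraries are set by the pseudocount, since those genes are at 0 in cKO library A.

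An adjusted p under 0.05 was given to 51 genes in the authors' deposited table, 49 lower and 2 higher in cKO. The higher ones in the authors' deposited table were Cldn1, at a ratio of 2.93, and Col11a1, at 2.35. The list there included 9 of the 12 microglial markers, 3 of the 20 rod markers and 0 of the 13 cone markers. The first by p-value in the authors' deposited table was Cx3cr1, the fractalkine receptor of microglia, at a ratio of 0.190. All 51 of these genes were among the 76 called by limma without cKO library A.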

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

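The limma count of 0 genes stayed at 0 with other pseudocounts, filters, rescaling, no trend and edgeR, became 2 with DESeq2, and ranged from 0 to 5662 when each library was left out; the cause was not tested. Array weights and the tools with a block were chosen after seeing the data. The tags are shared numbers that no label ties to an experiment, and the deviations of same-tag libraries correlate at 0.258 across genes. With the replicate block the count was 0 in limma (1375 genes at an unadjusted p under 0.05) and edgeR (965) and 43 in DESeq2, 2 higher (Col11a1 and Nell2) and 41 lower, Nr2e3, Pitpnm3, Hmha1 and Gnb3 among them. The lower ones in DESeq2 also held the microglial list members Laptm5, Cx3cr1, C1qa, C1qb, C1qc and P2ry12. The 8 list calls became 0 with an estimated correlation and ranged from 4 to 9 when each library was left out. Mueller glia markers passed as higher with a mean of at least 50 (adjusted p = 0.0223) and with the block (0.0444) in camera of limma at the preset correlation. In the main fit the Mueller list had adjusted p = 0.620 in camera of limma with an estimated correlation. The log2 fold change of Casz1 ranged from −0.53 to −0.22 over left-out libraries, passing only without cKO library B (limma, adjusted p = 0.0260; 0.576 to 1.00 under the others). Genes that changed sign with a library left out were Pax6 (−0.64 to 0.35), Mki67 (−1.23 to 0.20), Chd4 (−0.10 to 0.21), Kdm5d (−3.22 to 0.21), Eif2s3y (−2.74 to 0.29), Uty (−2.04 to 0.36) and Ddx3y (−1.56 to 0.30). The depth of cKO library A, 22326119 reads, limits genes of low level most.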

Other observations

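The tests of cKO library A alone and of a common ratio for the microglial markers, and the comparison of photoreceptor with other postmitotic markers, were chosen only after the results were seen. The mixing test was planned before its result was seen, but the reading of its intervals was changed after it, from undecided because the rod interval is wide to the bound first written, that each share lies within the other's interval. The inflammatory and metallothionein genes named next were also chosen after their values were seen.

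Several genes of the inflammatory response had values that differed by tag as well as by group, given as values. Between the tags limma called 0 of 14480 genes, with 757 at an unadjusted p under 0.05. That fit had no group term, so differences between the groups counted as spread in it. Tnfaip3, an inhibitor of NF-kB signalling, had normalized counts of 1541 and 3138 in the wild-type libraries A and B and of 279 and 1301 in the cKO libraries A and B. Nfkbiz, a regulator of NF-kB, had 1099 and 2130 in wild type and 207 and 1036 in cKO. Ccl3, a chemokine of activated microglia, had 767 and 2113 in wild type and 2.79 and 799.9 in cKO, the 2.79 being 1 read. The metallothionein Mt1 followed the tag more than the group, with 276 and 1144 in wild type and 176 and 918 in cKO. Of the genes linked to the Y chromosome, Kdm5d had 1969 and 2759 in wild type and 249 and 2691 in cKO. In the same order Eif2s3y had 3486, 5906, 679 and 5531, Uty had 785, 1057, 221 and 1168, and Ddx3y had 2322, 3359, 944 and 3450. All of these were lowest in cKO library A. Their log2 ratios of cKO to wild type were −2.98 to −1.30 at tag A and −0.09 to 0.14 at tag B. As a check, cKO library A thus differs from the other libraries in Y-linked transcripts, and the cause was not tested.

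cKO library A stood apart from the other libraries, with 9179 genes at 0. Lower depth alone is argued against, since the other libraries drawn down to its reads in 20 draws each had at most 6805 genes at 0. GC content and transcript length are argued against as the main source over all genes, since a smooth trend on both took up 0.377% of the variance of its deviations. The same trend took up 12.2% in the wild-type pair. Genes of low level scatter most in cKO library A, so this share cannot speak for well-measured genes. The median deviation was 0.13 in the 2872 shortest genes and −0.24 in the 2872 longest. Few starting RNA molecules stay open as a candidate explanation, which the scatter does not decide. The scatter in the 2896 genes of lowest level was 6.62 times that in the 2896 of highest level, against 4.47 in cKO library B drawn down to the same reads. Of the lowest 2896, 1021 were at 0 in cKO library A, against 37 after drawing down, so the pseudocount sets part of that ratio. The scatter was also wider in the highest 2896, at 0.44 (median absolute deviation) against 0.13 after drawing down. No biological explanation was tested for a single library.

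Microglial markers were lower in the GFP-positive libraries. An origin in cKO library A alone is argued against, since 12 of 12 were lower in cKO library B too. Fewer microglia among the GFP-positive cells may account for the pattern at tag B. The markers were lower there by about 1 common ratio, to a median of 43.3% of wild type. Their log2 ratios had an SD of 0.158, against 0.308 within the wild-type pair. A common ratio was not tested at tag A, where the median was 5.34% of wild type. The log2 ratios at tag A ran from −2.91 (Tyrobp) to −8.56 (Ptprc). Ptprc and Aif1 were at 0 in cKO library A, so the pseudocount sets part of this range. The 4N gate would remove microglia that were not dividing, other than doublets, and its purity was not tested. GFP-negative cells mixed into cKO library B may account for its smaller difference. The mixing share was 40.6% from rod markers (95% bootstrap interval over markers 17.1 to 57.8) and 39.5% from microglial markers (37.2 to 42.1), which takes cKO library A as unmixed. Both intervals take markers as independent, although the estimated correlation was 0.991 for microglial markers, so the narrow microglial interval overstates precision. Neither interval measures the spread between libraries. An effect of Casz1 loss on microglial transcripts was not tested, because GFP and genotype go together in these samples.

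Photoreceptor genes were lower in the GFP-positive libraries. An origin in cKO library A alone is argued against, since 19 of 20 rod markers were lower in cKO library B than in wild-type library B. A loss of postmitotic cells of every type to the same degree is argued against by the medians only. The median log2 fold change of 32 rod and cone markers lay −0.74 from that of 33 ganglion, amacrine and horizontal markers. The difference was −0.66 at tag A and −0.71 at tag B. A permutation test over genes gave p = 0.0001. It takes markers as independent, although the estimated correlation was 0.370 for cone and 0.744 for ganglion markers. That p does not measure the spread between the libraries of a group. A lower share of photoreceptor precursors in the GFP-positive 4N gate and a lower level per cell both stay open, as untested. The genotype and the GFP gate differ together, so neither can be assigned.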
